A study of Rattus norvegicus with 4 samples.

How the data were processed

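Articular cartilage of the proximal tibia was taken from 2 Sprague-Dawley rats aged 10 weeks. Per the labels' protocols, frozen tissue was cut into sections and 2 areas were collected separately by laser microdissection (LMD), which cuts chosen areas out of a tissue section: the superficial zone (SFZ) at the joint surface and the deeper layers (deep AC). RNA was extracted with a PicoPure kit, copied linearly with a RiboAmp HS PLUS kit and made into Illumina TruSeq libraries. This gave 4 libraries, 1 of each zone from each rat. How the borders of the captured areas were set is not given in the sources used here. Amplified RNA gives many reads per starting molecule, so intervals and floors computed from reads cover counting error only.

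The deposited values are log2 values, 1 per gene row and library, in a single table of 31007 rows. Per the file headers the rows carry gene identifiers, symbols and positions, and the title the authors gave the table names TMM (trimmed mean of M values) scaling, which sets a single factor per library. The build is rn4, per the submitters' processing notes. The aligner and the counting program are not given in the sources used here, nor is whether reads were counted by strand, so overlapping genes, antisense genes and near-identical gene copies could share reads. The values themselves showed how they had been made. Every row's median over the 4 libraries was within 1e-05 of 0, and 20218 rows were 0 in all 4, so levels had been removed and differences between libraries kept. In the 1397 rows above 0 in a single library, the value was the log2 of a whole number times a constant of that library for 93.98% to 96.75% of rows, to a relative tolerance of 1e-05. The deposited log2 values are thus scaled read counts with everything under 1 set to 1, less the row's median. The constant, the scaled value of 1 read, was 1.02 in SFZ rat 1, 1.00 in SFZ rat 2, 0.996 in deep AC rat 1 and 0.923 in deep AC rat 2. In SFZ 1 read is therefore above the floor and a library at the floor had no whole read. In deep AC 1 read is under 1 and was set to the floor too, so there the floor is 0 or 1 read. Some values were fractions, such as 158.4 reads of Cdh13 in SFZ rat 2, and a fraction of 1 read would also be at the floor. For SFZ, 0 reads is written for a library at the floor. No columns of other samples were in the table. 22 symbols had been turned into dates by spreadsheet software and were not used as names, and 318 symbols stood on more than 1 row.

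Levels were recovered from this structure. In 3375 rows at least 1 library sat at the floor, which fixed the level and the reads of the others. In the 7414 rows with no floor value, whole reads in all 4 libraries that matched the 3 differences to a relative tolerance of 1e-06 were searched, and 72.4% had a match, against 4 rows after the differences had been jittered by up to 0.01. 5129 rows were taken as resolved, with a sum of at most 20000 reads, 839 took their level from the binary places of the deposited values, and 1446 high rows had a level known only as a bound. Tested on simulated data, the search gave the true reads in 91.2% of resolved rows. It gave the true reads or their division by a common whole number in 100% of them. The simulated reads were all whole, so these shares do not cover rows with fractions of reads. Of the real rows with the floor known and 4 values other than 0, 94.7% were whole in every library. Reads are therefore printed only where the floor fixed them; differences between libraries do not depend on the level. The reads in rows with the floor known or reads resolved summed to 3259829 in SFZ rat 1, 3386348 in SFZ rat 2, 3095971 in deep AC rat 1 and 3443019 in deep AC rat 2. Those of resolved rows are known up to such factors, and the total depth is unknown. Rows above the floor numbered 8262, 8390, 10026 and 9237 in the same order.

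The design fixed before the data were examined had assumed normalized values with 1 added before the log. The table held log2 values with a floor at 1, so these were tested as they stand, with nothing added, and the recovered level served for the minimum level and for the trend of the spread. The rule that sets the level was settled after counts of calls had been seen; 2 other rules and a fit with 1 added are among the alternatives. Rows with a mean of at least 10 scaled reads over the 4 libraries were tested, 8794 in all. limma 3.58.1 in R 4.3.3 was fitted to the 4 libraries with the zone and the rat as terms (lmFit, then eBayes with trend=TRUE and robust=FALSE), which left 1 residual degree of freedom. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg, and the threshold was an adjusted p of 0.05. The rat was kept as a block because the sample titles tie both areas to the same animal. As a check, the correlation across genes of the difference between the 2 SFZ libraries with that between the 2 deep AC libraries was 0.05, and genes are not independent replicates. A ± gives the SD over the 2 rats. A fold against SFZ with no reads was computed against a floor of 3 reads over the zone and is written as "at least"; with 1 to 3 reads the ratio has an exact interval at a confidence level of 95%. No fold bound or ratio is given where a deep AC library was at the floor.

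38 gene lists were fixed before any value was seen, holding 831 different genes, of which 771 were found by symbol, 17 by Entrez identifier and 43 had no row and were not analysed here. The reference gene table of the GRCr8 assembly served for names only. Lists with at least 3 tested members, 35 in all, were tested with camera of limma, which compares a list with all other genes, with a preset correlation between genes of 0.01 and again with an estimated correlation. Members past the test were counted over all genes tested and adjusted over the list alone. The neutrophil and myeloid progenitor list had 0 tested members, and the lymphoid and endothelial lists had 2 each. Genes were named by a rule: per direction 15 genes past the threshold with the largest change, filled where fewer passed with genes ranked by the smaller of their 2 within-rat differences; always Prg4, Clu, Col2a1, Acan, Col10a1, Sox9, Ihh and Comp; and up to 4 members per list. Genes named outside this rule were chosen after their values had been seen, and the text says so.

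The procedure was tested on simulated data, with levels and noise taken from the recovered table. As its level rule was settled after counts of calls had been seen, this was not a test made beforehand. With noise as in the table and 8330 simulated genes fitted, limma called 0 of 8142 unchanged genes, 0 of 47, 0 of 45 and 0 of 46 genes changed by 1, 2 and 4 on the log2 scale, and 27 of 50 changed by 8. With 0.1 of that noise variance and 7920 genes fitted, it called 1 of 7735 unchanged genes and 5 of 46, 26 of 43, 34 of 46 and 50 of 50 at the same sizes. In both simulations camera with the preset correlation found both planted lists, and 5 and 3 of 200 random lists had a p under 0.05. The simulated noise was independent between genes and equal in both zones, so these rates do not cover lists whose genes vary together. With an estimated correlation camera found 0 of the 2 planted lists in the noisier simulation and 1 of the 2 in the other. That estimate rests on 1 residual degree of freedom, so a list that does not pass with it has not been shown to be unchanged.

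Alternatives were no block, another pseudocount, no minimum or a mean of at least 100 scaled reads, scaling by the median of log ratios, quantile normalization, other settings of the prior, each library left out, an adjusted p of 0.1, and a count with no test of genes at least 2-fold apart the same way in both rats. Fits with voom, with other level rules and on known reads alone were added after seeing the data. Groups of 2 libraries allow no test of other splits and no outlier test. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for recovery and figures.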

Results

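RNA-seq profiles of the superficial zone (SFZ) and of the deeper layers (deep AC) of tibial articular cartilage were compared in 2 adult rats, to find how gene expression differs between the surface of the tissue and the layers under it. Each rat gave 1 library of each zone, so there were 2 libraries per zone and 2 within-rat differences per gene. All values are SFZ minus deep AC on the log2 scale unless stated, and coordinates are of rn4. A library at the table's floor of 1 scaled read had 0 reads of the gene in SFZ and 0 or 1 read in deep AC, or a fraction of 1 read in either. The floor does not tell these apart, and differences taken against the floor depend on it. Of 31007 gene rows, 8794 reached the minimum level and were tested.

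Frzb, which encodes a secreted antagonist of WNT ligands (Entrez 295691, chromosome 3, 63350505 to 63383436, minus strand), fell in SFZ, with differences of -11.35 in rat 1 and -11.54 in rat 2. Its mean difference was -11.45 ± 0.14 (SD, n = 2 rats; SE 0.51; limma adjusted p = 0.029). It was the only gene of 8794 past the limma threshold. Its level was taken from the binary places of the deposited values, not from known reads. The trend of the spread uses that level, so the call depends on it. The same holds for Tnni2 and Ibsp below. The next genes all had an adjusted p of 0.0684: Tnni2 at -9.66 and -10.47, Ibsp, which encodes bone sialoprotein, at -8.75 and -10.27, and Polrmt, Apc2, Mal and Myoc, which were singled out after their values had been seen. Polrmt stood at -6.42 and -5.88, Apc2 at -6.48 and -5.97, Mal at -6.57 and -6.23, and Myoc, which encodes myocilin, at 5.67 and 4.84. By limma 0 genes passed as higher in SFZ. On genes with known reads, which do not include Frzb, limma called 0 higher and 0 lower with voom weights and 3 higher and 4 lower without them. At an unadjusted p under 0.05, limma on all 8794 genes had 376 higher and 486 lower, 9.80% of those tested. The Frzb call was lost without any 1 of the 4 libraries (adjusted p = 0.152 and 0.150 without SFZ rat 1 and rat 2, 0.172 and 0.224 without deep AC rat 1 and rat 2, in limma fits with no rat term), with a pseudocount of 0.1 (0.0993), with no minimum level (0.0728) and with an untrended prior (0.251). Its adjusted p over the alternatives ran from 2.12e-09 with quantile normalization to 0.251.

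Among the other genes with the lowest values in SFZ, none of which passed the test, several had no read or a few reads there. Grem1, an antagonist of bone morphogenetic proteins on chromosome 3 (99597201 to 99608935), had 1 and 0 reads in SFZ against 1662 and 2265 in deep AC, a scaled ratio of 3725 (exact interval 668 to 147164; limma adjusted p = 0.186). F5, coagulation factor V, had 0 reads in both SFZ libraries and 1078 and 1038 in deep AC, at least 670-fold lower. Phospho1, a phosphatase of matrix mineralization on chromosome 10 (84535187 to 84542722), had 0 and 0 against 287 and 642 reads, at least 289-fold lower. A2m, a protease inhibitor, was at least 313-fold lower and Foxa2, a forkhead transcription factor, had 0 and 2 against 586 and 804 reads (ratio 659, 182 to 5449). Evi2a had 0 and 1 against 615 and 326 reads (ratio 893, 160 to 35292). Rarres1 stood at -10.52 and -10.92. Etnk2, Arhgap18, Nudcd1, Kcnk6 and Amhr2 were at least 342-fold, 360-fold, 176-fold, 163-fold and 179-fold lower, all from 0 reads in both SFZ libraries.

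The genes with the highest values in SFZ, none past the test, included Prss23, a serine protease gene on chromosome 1 (146081552 to 146089928), with 517 and 557 reads in SFZ, while both deep AC libraries were at the floor of 0 or 1 read (limma adjusted p = 0.283). No fold bound is given against that floor. Kcnj8, which encodes an inwardly rectifying potassium channel, had 417 and 351 reads in SFZ and was at the floor in both deep AC libraries. Wnt9a, a WNT ligand gene of developing joints on chromosome 10 (45613668 to 45641488), had 119 and 600 reads in SFZ and was also at the floor in both. Cidea, a lipid droplet protein gene, had 318 and 864 reads in SFZ, 2 in deep AC rat 1 and the floor in deep AC rat 2, and Cldn11, a claudin, stood at 7.70 and 9.43. Tmem176a with 735 and 85 reads in SFZ, Gldc with 355 and 65, Lrrc52 with 190 and 352, and Bend5 with 189 and 330 were at the floor in both deep AC libraries, as were Cdh13 at 8.74 and 7.31 and Gp1bb at 7.11 and 5.94. Htra4 stood at 6.35 and 8.11, Pion at 7.30 and 6.37, Fbxo43 at 6.10 and 6.69, and Aifm3 at 6.16 and 6.35.

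**Figure D1:**
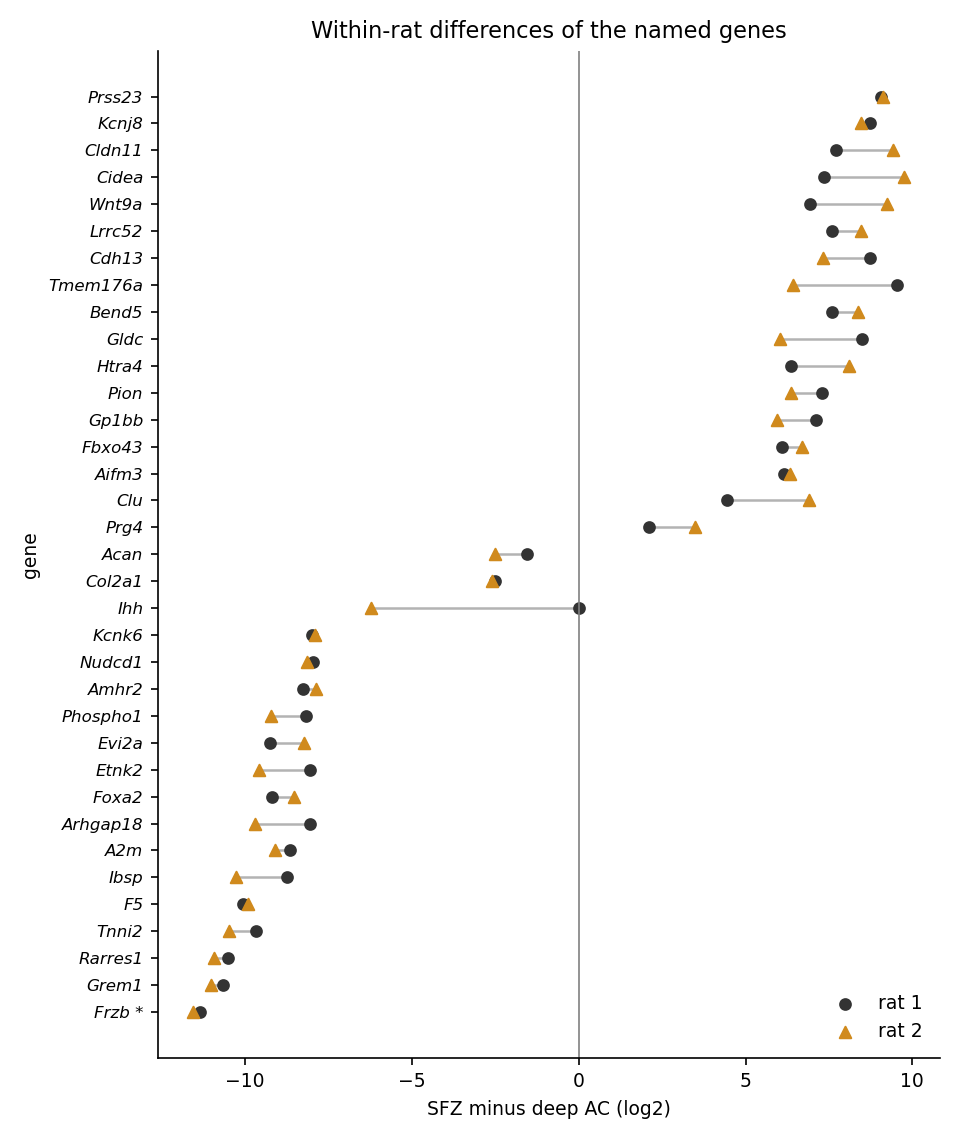
Within-rat differences (SFZ minus deep AC, log2) of the named genes with a value in the fit, circles for rat 1 and triangles for rat 2, with a grey line between them; the asterisk marks Frzb, the gene past the limma threshold. Genes at the floor in a zone are drawn against the table's floor of 1 scaled read. Frzb stood at -11.35 and -11.54 and Prss23 at 9.05 and 9.12, while Ihh was at 0 in rat 1 and at -6.22 in rat 2.

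Genes at least 2-fold apart in the same direction in both rats were more often lower than higher in SFZ. 1047 genes were lower and 564 higher, 65.0% lower, where independent lists would share 658 and 365; 984 genes were at least 2-fold apart in opposite directions. With quantile normalization the numbers were 843 lower and 791 higher, 51.6% lower, and that scaling moved the median of all genes from -0.13 to 0.01 in rat 1 and from 0.00 to 0.06 in rat 2. SFZ libraries were at the floor for more of the tested genes, 872 in rat 1 and 796 in rat 2, than deep AC libraries, 189 and 352. 291 genes were at the floor in both SFZ libraries and above it in both deep AC libraries, against 27 the other way round.

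The differences in the 2 rats were weakly correlated across genes (Pearson's r = 0.25, Spearman's rho = 0.17), and 54.1% of genes had the same sign; genes are not independent replicates. The 2 SFZ libraries differed more from each other (SD of the log2 difference over genes 2.71) than the 2 deep AC libraries (1.45), and the mean difference between zones had an SD of 1.94. Across genes, levels had a Spearman's rho of 0.81 between the SFZ libraries, 0.93 between the deep AC libraries, and 0.84 and 0.82 between the zones of rat 1 and rat 2.

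**Figure D2:**
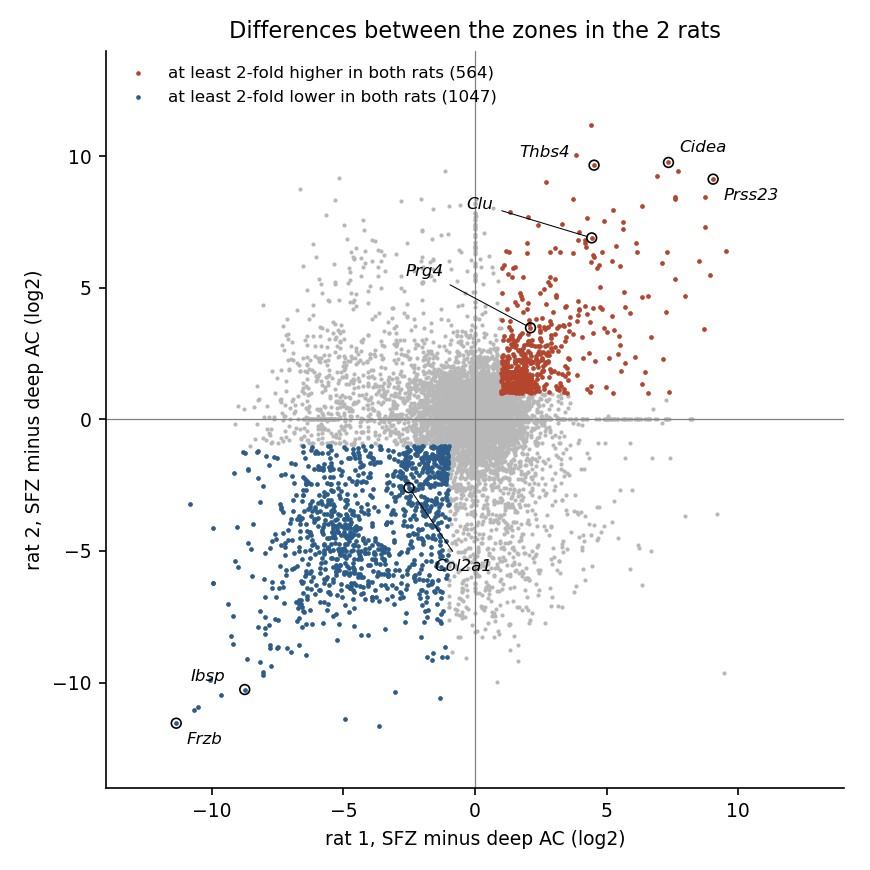
Differences between the zones in rat 1 (horizontal, SFZ minus deep AC, log2) and rat 2 (vertical, same scale), 1 point per tested gene; red and blue points are at least 2-fold higher (564) or lower (1047) in both rats and grey points are the rest. Lines of points on the axes are genes at the floor in both libraries of a rat.

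Genes of the superficial zone were higher in SFZ as a list. Prg4, which encodes lubricin, the lubricant of the joint surface (chromosome 13, 64753316 to 64769533), stood at 2.11 and 3.48, and Clu, which encodes clusterin, at 4.43 and 6.89. Cilp, a cartilage intermediate layer protein gene, stood at 2.09 and 2.52, and Cilp2 at 0.35 and 1.06. Of 8 tested members of the superficial zone list, 6 were higher in both rats and none was lower in both, with medians of 2.10 and 3.0 (camera of limma, adjusted p = 5.61e-05; adjusted p = 0.790 with an estimated correlation). No member passed over all genes tested, and 4 did adjusted over the list alone: Clu, Cilp, Prg4 and Thbs4. On genes with known reads alone, which leaves out all 4 of them, the list had an adjusted p of 0.740.

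Markers of synovial and tendon fibroblasts were also higher in SFZ as a list, though members went both ways. Thbs4, a thrombospondin gene of tendon that is also in the superficial zone list, stood at 4.52 and 9.65, Col15a1 at 1.74 and 2.25, Pdgfra at 0.53 and 1.53, and Clic5 at 7.41 and -1.47. Of 14 tested members, 7 were higher in both rats and 3 were lower in both, with medians of 1.13 and 2.0 (camera of limma, adjusted p = 0.00149; adjusted p = 0.790 with an estimated correlation). None passed over all genes, and 4 were higher adjusted over the list alone. On genes with known reads alone the adjusted p was 0.0566. Beside these 2 lists, the macrophage list had medians of 3.53 in rat 1 and 0.00 in rat 2 (camera of limma, adjusted p = 0.176). Of its 11 tested members, 2 were higher in both rats and 2 were lower in both. Lyz2 stood at 3.53 and 0.43, Ptprc at -2.03 and -1.02 and Mrc1 at -1.63 and -0.15. C1qa and C1qb, complement genes of macrophages singled out after their values had been seen, had 119 and 91 reads in SFZ rat 1. Both were at the floor in the other 3 libraries.

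Matrix genes of hyaline cartilage were lower in SFZ as a list. Col2a1, which encodes the main collagen of cartilage (chromosome 7, 136679219 to 136707976), stood at -2.51 and -2.60, a mean of -2.55 ± 0.06 (SD, n = 2 rats), and Acan, which encodes aggrecan (chromosome 1, 134787341 to 134848992), at -1.55 and -2.52. The type IX collagen genes Col9a1 and Col9a2 stood at -2.54 and -3.19 and at -3.38 and -2.69, and Mia, a secreted cartilage protein gene, at -5.44 and -3.53. Of 19 tested members, 12 were lower in both rats and 4 were higher in both, with medians of -1.38 and -0.83 (camera of limma, adjusted p = 0.000319; adjusted p = 0.790 with an estimated correlation). None passed over all genes, and 9 were lower adjusted over the list alone. Collagen processing enzymes were lower in both rats for 12 of 17 members and higher in both for 0, with medians of -0.47 and -0.32, and the list did not pass (adjusted p = 0.0587). It passed without the rat term (0.0322), with a mean of at least 100 scaled reads (0.00896) and with quantile normalization (0.0308). Its members Lepre1 and Serpinh1, which encode a prolyl hydroxylase and a collagen chaperone, stood at -1.20 and -1.12 and at -1.08 and -0.61. Sox9 was listed at 0 in all 4 libraries, and whether it had no reads, was at the floor or was not counted is not known here. Comp was not analysed here.

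Most tested markers of the hypertrophic and calcified zones were lower in SFZ. Ibsp and Phospho1 have been given, Pth1r, the receptor of parathyroid hormone, stood at -2.81 and -2.60, and Clec3a at -1.57 and -1.54. Enpp1, which makes the mineralization inhibitor pyrophosphate, stood at 0.22 and 0.46. Ihh, which encodes Indian hedgehog, had 81 reads in deep AC rat 2, was at the floor in deep AC rat 1 and had 0 reads in both SFZ libraries, so its difference rests on rat 2 alone. Col10a1 was listed at 0 in all 4 libraries, for a reason that is not known here, as for Sox9. Of 11 tested members, 8 were lower in both rats and 1 was higher in both, with medians of -2.81 and -4.47 (camera of limma, adjusted p = 5.61e-05; adjusted p = 0.790 with an estimated correlation). The median of the mean differences was -3.11, the value of Ihh, and was the same with the genes that have a fold bound set to it. None passed over all genes, and 6 were lower adjusted over the list alone, among them Ibsp, Alpl, Pth1r, Phospho1 and Clec3a. Mineralization regulators had medians of -0.06 and -3.79 (adjusted p = 0.112), with 5 lower and 1 higher adjusted over the list alone; the higher one was Mgp, which encodes the calcification inhibitor matrix Gla protein, at 2.97 and 4.07. Beside these, the osteoblast and osteocyte list, which shares Ibsp and Alpl, had medians of -2.35 and -2.23 (camera of limma, adjusted p = 0.112). Of its 10 tested members, 4 were lower in both rats and 3 were higher in both, among the latter Col1a2 at 0.99 and 0.45. With quantile normalization the mineralization list (0.00627) and the osteoblast list (0.0353) passed.

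WNT antagonists were lower in SFZ as a list. Besides Frzb, Wif1, a WNT inhibitory factor gene, stood at -1.94 and -1.68, Dkk1 at -3.33 and -3.90, and Sfrp5 at -1.49 and 0.18. Of 5 tested members, 3 were lower in both rats and none was higher in both, with medians of -3.33 and -1.68 (camera of limma, adjusted p = 0.00065; adjusted p = 0.790 with an estimated correlation). Frzb passed over all genes, and Frzb and Wif1 passed adjusted over the list alone. The WNT ligands, receptors and targets, which include Wnt9a, did not pass, with medians of 0.04 and 0.06 over 16 members (adjusted p = 0.507).

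Genes of the EGF and ERBB pathway were higher in SFZ as a list, though not every member was. Hbegf, which encodes a heparin-binding EGF receptor ligand, stood at 4.50 and 6.24, Errfi1, a feedback inhibitor of the receptor, at 4.65 and 5.76, Egf at 1.46 and 1.33, and Tgfa at -0.71 and 1.38. Of 7 tested members, 4 were higher in both rats and none was lower in both, with medians of 0.19 and 1.38 (camera of limma, adjusted p = 0.0128; adjusted p = 0.790 with an estimated correlation). None passed over all genes, and Hbegf did adjusted over the list alone.

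Genes of lipid and cholesterol metabolism were lower in SFZ as a list, though not every member was. Cyp51, an enzyme of cholesterol synthesis, stood at -1.49 and -2.98 and Scd, a fatty acid desaturase gene, at -2.22 and -1.36, while Acly stood at 0.49 and 0.81 and Srebf2, a regulator of sterol synthesis, at 0.24 and 0.10. Of 20 tested members, 11 were lower in both rats and 2 were higher in both, with medians of -0.48 and -1.44 (camera of limma, adjusted p = 0.0034; adjusted p = 0.790 with an estimated correlation). None passed over all genes, and 3 were lower adjusted over the list alone, among them Cyp51 and Scd.

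**Figure D3:**
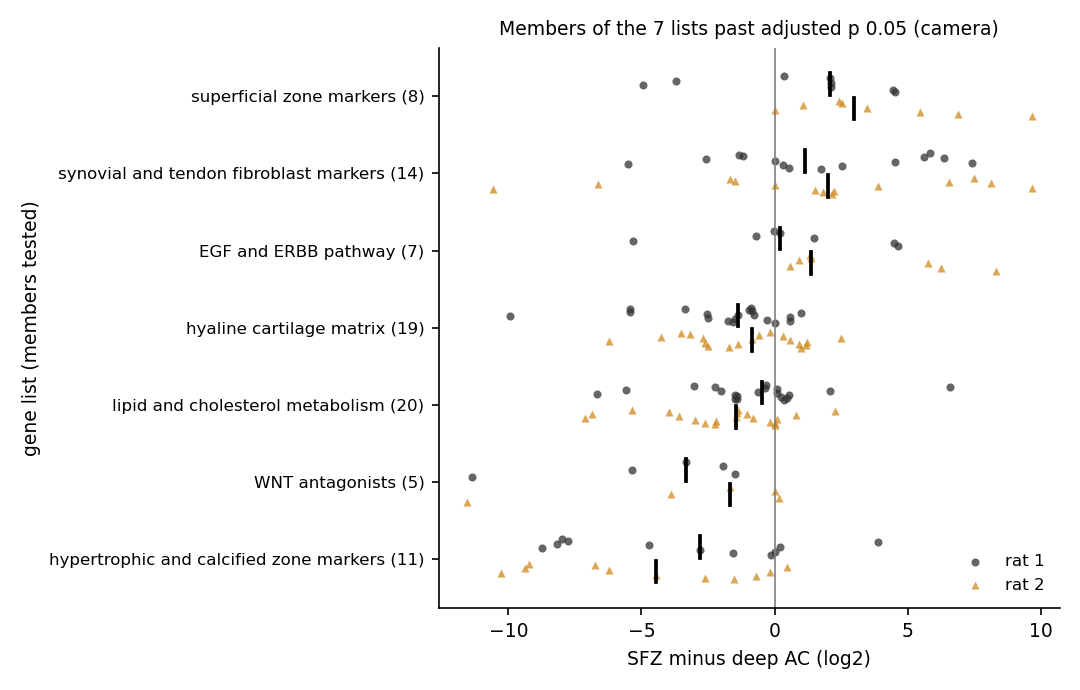
Differences (SFZ minus deep AC, log2) of the tested members of the 7 lists past an adjusted p of 0.05 in camera with the preset correlation, circles for rat 1 and triangles for rat 2; points are spread vertically for visibility and black bars mark each rat's median. The medians lie from -2.81 and -4.47 for hypertrophic and calcified zone markers to 2.10 and 3.0 for superficial zone markers. With an estimated correlation, a test that rests on 1 residual degree of freedom, none of the 7 passed.

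The remaining matrix and transcription factor lists did not pass camera of limma. Fibrous and interstitial matrix genes had medians of -0.36 and -0.47 over 21 members (adjusted p = 0.221), with Fn1, which encodes fibronectin, at -1.17 and -1.85 and Sparc at -1.95 and -1.48. Chondrocyte transcription factors had medians of -0.33 and -0.70 (adjusted p = 0.221), with Trps1 at 0.42 and 0.42 and Hif1a at -0.69 and -1.18. Small leucine-rich proteoglycans had medians of -0.04 and 0.00, proteoglycan synthesis enzymes of 0.05 and -0.56, and matrix proteases and inhibitors of 0.32 and 0.05 (each adjusted p = 0.938). Fmod, which encodes fibromodulin, stood at 1.0 in both rats, Bgn, which encodes biglycan, at -0.71 and -1.13, Csgalnact1 at 1.85 and 1.99, and Mmp3, a matrix protease gene, at -10.84 and -3.21. Adjusted over the list alone, 1 fibrous matrix gene and 1 transcription factor were lower, and 1 protease list member was higher and 5 were lower.

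The other signalling lists did not pass camera of limma either. TGF-beta and BMP ligands and receptors had medians of 0.86 and 0.87 over 22 members (adjusted p = 0.130), with Bmp5 at 1.29 and 0.92 and Gdf10 at -3.84 and -5.04; it passed with quantile normalization (0.0379). The antagonists and targets of these pathways had medians of -0.17 and 0.00 (0.938), with Tgfbi at 1.60 and 2.26. The adjusted p was 0.938 for the hedgehog and PTHrP list (medians 0.00 and 0.49), 0.665 for the FGF and IGF list (-0.23 and -0.04), 0.498 for the Notch list (-2.0 and -0.04), 0.259 for YAP and SRF targets (0.13 and 0.42), 0.476 for ion channels (-0.24 and 0.08) and 0.977 for joint inflammation and complement (0.18 and 0.01). Fgfr2, a growth factor receptor gene, stood at 1.91 and 1.86, Igfbp5, an insulin-like growth factor binding protein gene, at 4.41 and 11.19, and Gja1, which encodes connexin 43, at 1.01 and 1.57. Adjusted over the list alone, the TGF-beta and BMP list had 1 higher and 1 lower, the antagonist list 1 higher and 2 lower, the hedgehog list 1 lower, the FGF and IGF list 2 higher, the YAP list 1 higher, and the inflammation list 1 higher and 1 lower.

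None of the other 6 lists of cell state passed. Oxidative phosphorylation genes had medians of 0.14 and 0.21 over 33 members, ribosomal protein genes of -0.07 and -0.31 over 43, and hypoxia and glycolysis genes of -0.28 and -0.53 over 22 (camera of limma, each adjusted p = 0.221). With a mean of at least 100 scaled reads, the ribosomal protein list passed as lower (adjusted p = 0.0466). Cell cycle genes had medians of 0.00 and -0.04, immediate early genes of 0.27 and -0.58, and ER and heat stress genes of -0.22 and 0.03 (each adjusted p = 0.938). Tpi1, a glycolytic enzyme gene, stood at -0.47 and -1.17, Klf4 at 2.14 and 1.37, and Atf4 at -1.08 and -1.25. No member of these 6 lists passed adjusted over the list alone.

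Of the lists for other cell types not yet given, none passed. Erythroid markers had medians of 0.00 and 1.89 (camera of limma, adjusted p = 0.507), with the haemoglobin gene Hbb-b1 at -6.03 and 6.18. Osteoclast markers had medians of 0.03 and -1.26 (0.494), with Ctsk, which encodes cathepsin K, at -0.52 and -2.17. Adipocyte markers had medians of 1.21 and 4.79 over 4 members (0.176; 0.0466 with quantile normalization), with Pnpla2, a lipase gene, at 4.17 and 4.30 and Cidea higher adjusted over the list alone. Skeletal muscle markers had medians of -2.69 and 2.72 (0.418), with Tnni2, which encodes fast skeletal troponin I, lower adjusted over the list alone and Ckm, a muscle creatine kinase gene, at 0.00 and 6.59. Of the lists too short to test, the lymphoid members Vpreb1 and Cd79b stood at -0.76 and 0.46 and at 0.00 and 7.83, and the endothelial members Egfl7 and Pecam1 at -4.68 and -2.34 and at -0.94 and 0.16. The median and mean of the mean differences had opposite signs for the protease (0.54 and -1.30), BMP antagonist (0.07 and -0.80), hedgehog (0.12 and -0.17), YAP (0.23 and -0.34), inflammation (0.12 and -0.41), ion channel (-0.19 and 0.00) and skeletal muscle (0.02 and -1.68) lists.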

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

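Fits with voom, on known reads alone and with other level rules were chosen after seeing the data. Without the rat term (no replicate block) 0 genes were higher and 1 lower, and collagen processing passed as a further list (adjusted p = 0.0322), 8 lists in all; the pairing by rat changed no other call. Counts higher and lower, against 0 and 1, were 0 and 0 with a pseudocount of 0.1, 2 and 8 with 5, 0 and 0 with no minimum level, 0 and 0 with trend=FALSE, 1 and 6 with the median of log ratios, 71 and 113 with quantile normalization, 2 and 7 at an adjusted p under 0.1, and 564 and 1047 with no test. With voom on genes with known reads, which excluded Frzb, they were 0 and 0, with matches of any total 0 and 4 (Frzb, Tnni2, Ibsp and Alpl), and with known reads alone, again without Frzb, 3 and 4. Leaving out 1 library gave 0 to 1 higher and 0 to 403 lower: 365 without deep AC rat 1 and 403 without deep AC rat 2, and 0 without SFZ rat 1 or rat 2; the lone library is assumed to vary like the other zone. Most of the lower genes without deep AC rat 1 had the same or nearly the same value in both SFZ libraries. This leaves little or no spread of their own to test against. Ccne1, Spon1, Rnf4 and Hmx2 were among them, at only -0.88 in that fit. Such calls do not show genes lower in SFZ. The cause of the other changes was not tested.

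Of the 7 lists, none turned direction where it was tested. With an estimated correlation 0 passed, but that test rests on 1 residual degree of freedom and decides little. With quantile normalization 12 lists passed. With known reads alone 4 of the 7 passed, the superficial zone (0.740) and fibroblast (0.0566) lists did not, and WNT antagonists had fewer than 3 members and were not tested. Known reads leave out Prg4, Clu, Cilp and Thbs4. The correlation of the rats ran from 0.24 to 0.26 over another minimum and pseudocounts and was 0.21 with the rat numbers crossed. Of the 30 genes named by size, 18 were named again with a pseudocount of 0.1, 17 with 5, 18 with quantile normalization, and 13 to 14 from 1 rat alone. The planned count tests of edgeR and DESeq2 were not run, since raw counts were not used here. Noise between the libraries limits what limma can call: in simulations it called 0 of 45 genes changed by 2 on the log2 scale with noise as in the table and 26 of 43 with 0.1 of that variance. The total depth is unknown and its effect was not tested.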

Other observations

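The tests of gene families and GO terms, of blood markers and of macrophage markers and the shift of all differences were chosen after the results had been seen. Among 120 families of genes with the same symbol stem, camera of limma called 1, the protocadherin gamma A genes, which encode cell adhesion proteins from a cluster on chromosome 18. All 10 tested members, from Pcdhga1 (30568805 to 30754205) to Pcdhga12 (30673815 to 30754205), were higher in SFZ in both rats, with medians of 1.25 and 1.64 (adjusted p = 0.0248), and the next family had an adjusted p of 0.416. The 10 genes end at the same position and most had the same value, as genes counted from shared 3' exons do, so they count as a single measurement with uncertain reads. Of 1269 GO terms, camera called 0, with 59 at an unadjusted p under 0.05 and a smallest adjusted p of 0.291.

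More genes were 2-fold lower than higher in SFZ in both rats. The shift of 0.32 in every difference that would give equal numbers left 25.1% lower (interval 20.2 to 30.5 over 291 genes) among genes with a mean of at least 1000 scaled reads, which argues against a single factor per library as the whole cause. That shift could only lower the 46.1% these genes had without it, so it is not evidence apart from that share. The median of log ratios left 66.0% lower (63.6 to 68.3 over 1592 genes). It moved the differences by only 0.03 and -0.07, too little to test scaling. Quantile normalization gave 51.6%, but it gives all libraries the same distribution and so can remove such an excess whatever its cause. That share therefore does not test scaling that depends on the level, which stays open. With no shift the share among genes with a mean of at least 1000 scaled reads was 46.1% (39.4 to 53.0 over 219 genes, which are not independent), so loss of low-level transcripts from the SFZ libraries may account for the excess. Among genes with 10 to 100 scaled reads in the lower deep AC library, 217 were at the floor in both SFZ libraries, against 81 expected from independent loss. The other way round it was 15 against 0.69. Losses thus repeated in the same genes, but levels differ within that range. This does not tell loss from a difference between the zones in low-level genes, which stays open.

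Hypertrophic and calcified zone markers were lower in SFZ as a list in camera of limma with the preset correlation (adjusted p = 5.61e-05). Of 11 members 0 passed the test over all genes. The list did not pass camera with an estimated correlation (adjusted p = 0.790), but that test rests on 1 residual degree of freedom and decides little. The mineralization list passed camera with neither correlation (adjusted p = 0.112 and 0.790). Bone cells in the deep AC captures would bring Col1a1, Col1a2 and Bglap, whose median difference was 0.99 in rat 1 and 0.45 in rat 2 (0.451 the lower), with Col1a1 at 7.16 and 2.27, Col1a2 at 0.99 and 0.45 and Bglap, which was below the minimum level, at 0.00 and -1.02, where bone cells needed -1 or less. The medians met the value set against bone cells, 0 or above in both rats. The spread of the 3 genes (SD 3.88 and 1.65) exceeds these medians, however, so bone cells cannot be told apart from calcified cartilage here. Hypertrophic chondrocytes also express Ibsp and Alpl of the bone list. Dmp1 and Mepe of that list, singled out after their values had been seen, went the other way from Col1a1 and Col1a2. Dmp1 stood at -9.02 and -5.61 and Mepe at -4.75 and -3.79. Of the 10 tested members of the bone list, 4 were lower in both rats and 3 were higher in both. Marrow or blood cells would bring the median of their markers under -1 in both rats, while 0 or above was set against them. The median of 20 was 0.22 and 0.21 (0.214 the lower), but with SDs of 3.53 and 3.30, which leaves them open too. The 20 were 11 macrophage, 7 erythroid and 2 lymphoid markers, with 0 neutrophil or myeloid progenitor markers. The same 11 macrophage markers serve for the synovial lining below. The zone itself, which the design names, stays an untested explanation.

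The superficial zone and fibroblast lists were higher in SFZ in camera of limma with the preset correlation (adjusted p = 5.61e-05 and 0.00149). Neither passed camera with an estimated correlation (adjusted p = 0.790 each), a test that rests on 1 residual degree of freedom. Neither passed camera on known reads alone (adjusted p = 0.740 and 0.0566). Known reads leave out Prg4, Clu, Cilp and Thbs4, so that fit does not test these markers. Of 14 fibroblast markers, 3 were at least 2-fold lower in both rats. In both lists 0 members passed the test over all genes. Synovial tissue in the SFZ captures may add to the higher values of the 2 lists, since its lining also expresses Prg4. The fibrillar collagen genes Col1a1, Col1a2 and Col3a1 had a median of 0.99 in rat 1 and 0.45 in rat 2 (0.451 the lower, SDs of 3.75 and 1.11). This lay between the 1 set for synovial tissue and the 0 set against it. For macrophages of the synovial lining the median of 11 markers was 3.53 in rat 1 and 0 in rat 2 (0 the lower). Both sources stay open.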
